A study of Arabidopsis thaliana with 6 samples.

How the data were processed

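RNA was measured in 6 libraries from Arabidopsis thaliana root tips, 3 from wild-type plants and 3 from plants carrying the scl28-3 mutation. Per the labels, the tips were about 2 mm long, came from 6-day-old plants grown in continuous light at 21 °C, and about 300 tips were pooled per sample. The 3 samples of a genotype were given as biological replicates. Per the submitters' processing notes, HISAT2 2.0.0, HTSeq 0.6.1p1, edgeR and the TAIR10 genome were used. The annotation release, the edgeR version and whether counting used the strand were not given in the sources used here.

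The values deposited by the authors were CPM, read counts scaled to a fixed library total, per the file headers, rounded to 2 decimals. Each library's CPM summed to between 999949 and 999965, so the values were scaled to the library total and to nothing else. The tables listed 21125 genes, each above 0 in at least 3 of the 6 libraries, and 19401 of them were above 0 in all 6. Of the gene IDs, 21020 matched a locus of the reference annotation (TAIR10.1) and 105 did not. Symbols were taken from that annotation. It attaches the name SCL28 to a different locus, so SCL28 here means AT1G63100, for which it gives the product GRAS family transcription factor and no symbol.

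Within a library the low CPM values were whole multiples of a single step, the value of 1 read. Dividing by that step gave whole reads for 100% of values in every library, within 0.1 read. The recovered totals were 11572901, 10399899 and 11395977 reads in the wild-type libraries and 13996534, 14209063 and 16780424 reads in the scl28-3 libraries. A count of 3 reads corresponded to between 0.179 and 0.288 CPM, so values near these levels rest on few reads. No pair of libraries agreed within sampling noise in a chi-square comparison of reads over genes.

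The design fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test. Because the files held CPM, the main test was instead limma 3.58.1 with an intensity trend (lmFit and eBayes, R 4.3.3) on log2(CPM + 0.5), after dividing CPM by TMM factors from edgeR 4.0.16. Fold changes are on that log2(CPM + 0.5) scale, which understates the change of genes with low CPM. Genes were kept by filterByExpr on the recovered reads with its minimum count of 10, which left 17879 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The quasi-likelihood test on recovered reads was run as an added alternative and called 14 genes, against 13 in the main test. Errors of log2 fold changes are standard errors, and errors of CPM are SD over 3 libraries.

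The 27 gene lists were fixed before the data were examined. They held 384 entries, of which 2 were dropped because the reference gives the symbol to another locus. The core histone list and the list of expansins and XTH enzymes were filled from symbols of the reference. Lists were tested with camera at a preset inter-gene correlation of 0.01, then with a correlation estimated from the residuals and with fry, and adjusted over the 27 lists. Members were also adjusted over the list alone. Principal components were computed on the log2(CPM + 0.5) values of the tested genes, after the same division by TMM factors as in the main test.

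Genes were named by a rule fixed beforehand. It took SCL28, the 12 largest changes in each direction among called genes with an average log2 CPM of at least 1 and no overlap between genotypes, and up to 4 called members per list. It also took up to 2 members with the highest CPM that did not pass, for lists the text leads with, and any member of the SIM and SMR, KRP, mitotic cyclin and other G2/M lists. The low called genes AT1G43590, AT3G28510, AT3G01345 and AT4G04223 fell outside the level of that rule and were named after their values were seen, as were EXPA10, EXPA15 and XTH21. The values of 1 further gene are not reported here.

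Alternatives covered the test (DESeq2 1.42.0, the edgeR exact test, limma-voom), the scaling, the filter on low counts, a replicate block, thresholds and leaving out each library. Alternatives chosen after seeing the data were the quasi-likelihood test, pseudocounts of 0.1, 1 and 2, reads thinned at random to the depth of the shallowest library in 10 draws, and a fit with the level of the endodermis list as a covariate. The steps were tested on simulated data for the scl28-3 against wild type comparison, with 17758 genes tested. The fit called 25 of 49 genes changed 1.5-fold, 42 of 49 changed 2-fold, 47 of 49 changed 4-fold and 45 of 47 changed 8-fold. Of its 169 calls, 7 were genes simulated as unchanged. The simulated genes varied independently of each other within a library. With 169 calls the adjusted threshold was also looser than with the 13 calls in the data. These rates may therefore overstate the power of the real fit. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used to read the files.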

Results

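The transcriptome of root tips was compared between wild-type Arabidopsis and scl28-3, a mutant of SCL28, which encodes a GRAS-family transcription factor. The study asked what the loss of SCL28 does to gene expression in the root tip, where cells divide before they elongate and differentiate. Each genotype had 3 libraries, each from about 300 tips. Recovered depth ran from 10399899 to 11572901 reads in the wild-type libraries and from 13996534 to 16780424 reads in the scl28-3 libraries. On average the scl28-3 libraries were 1.35 times deeper, with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give.

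SCL28 transcript was lower in every scl28-3 library than in every wild-type library. The gene AT1G63100 lies on the minus strand of chromosome 1 from 23399112 to 23402176 in TAIR10.1. It was at 44.5, 42.59 and 42.38 CPM in wild type and at 17.72, 14.92 and 13.65 CPM in scl28-3. The means were 43.2 ± 1.17 and 15.4 ± 2.08 CPM (SD, n = 3 each), a log2 fold change of -1.48 ± 0.12 (SE) with a limma adjusted p = 0.0022. Transcript from the locus therefore remained detectable in the mutant libraries.

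Few other genes were called in the limma fit. Of 17879 genes tested with limma, 13 including SCL28 were called, and in this fit each was lower in scl28-3. None was called higher with this limma fit, edgeR's quasi-likelihood test, DESeq2 or limma-voom, while 394 genes were higher and 387 lower at an unadjusted p under 0.05, against 894 expected by chance in all. Other fits called more genes and some higher, with 38 lower and 8 higher in the edgeR exact test, 40 lower and 24 higher in limma with the sample numbers as a replicate block, and 24 lower and 3 higher in limma with the endodermis list level as a covariate. The number of genes at an unadjusted p under 0.05 also depended on the fit. It was 482 with DESeq2, 1966 with the replicate block and 2021 with the endodermis covariate. When a library was left out of the limma fit it ran from 393 (without scl28-3 library 3) to 1763 (without wild-type library 1). Among tested genes, 10.4% had no overlap between genotypes, where chance gives 10%. Of the 13 called genes, 11 differed at least 2-fold.

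The called gene with the lowest adjusted p was SADHU3-2 on chromosome 3, annotated as a pseudogene and named for the Sadhu retroelements. It fell from 11.3 ± 0.744 to 0.813 ± 0.272 CPM, a log2 fold change of -3.21 ± 0.19 with a limma adjusted p = 0.000412. AT5G26270, of unknown function, fell from 14.2 ± 3.37 to 2.03 ± 0.627 CPM, and ATGSTF13, a glutathione S-transferase, from 18 ± 2.48 to 5.25 ± 0.318 CPM. Among genes at higher levels, XTH5, a xyloglucan endotransglucosylase/hydrolase of the cell wall, fell from 84.7 ± 1.1 to 50.8 ± 4.2 CPM. ASPGB1, an asparaginase, fell from 20.6 ± 2.38 to 8.79 ± 1.47 CPM, and BGLU25, a beta glucosidase, from 80.6 ± 4.58 to 52 ± 1.1 CPM. The noncoding RNA AT5G38005 fell from 6.95 ± 1.89 to 1.53 ± 0.385 CPM. A group with low levels held the pseudogene AT1G43590, AT3G28510, AT3G01345 and the noncoding RNA AT4G04223. These 4 genes, named after their values were seen, were between 1.77 and 3.85 CPM in wild type and between 0.107 and 0.183 CPM in scl28-3.

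Calls depended on which library was left out. Without wild-type library 1 the limma fit called 18 genes lower, and without any other library it called 5 or 6. SCL28, SADHU3-2, AT5G26270, ATGSTF13 and AT1G43590 were called in each of those 6 fits. Of the 13 called genes, 2 overlap a gene on the opposite strand in TAIR10.1. BGLU25 shares 25 bases with EDA5, which was at 2.41 ± 1.09 CPM in wild type and 2.3 ± 0.531 CPM in scl28-3. AT5G26270 shares 209 bases with the noncoding RNA AT5G04225, which has no values here, so reads from that stretch are of uncertain origin if counting ignored the strand.

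**Figure D1:**
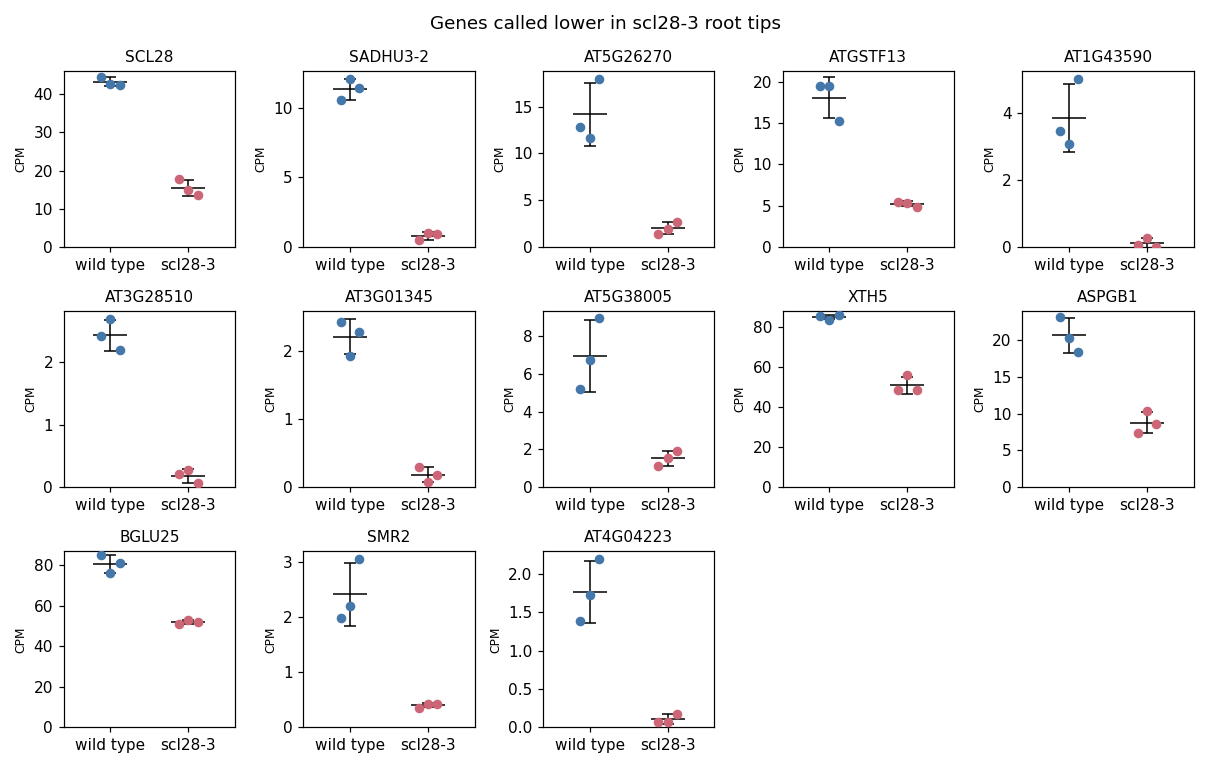
CPM of each of the 13 called genes (vertical axis, from 0) in the 3 wild-type and 3 scl28-3 libraries, with a point per library, the mean as a horizontal line and the SD as an error bar. In every panel the 3 scl28-3 libraries lie below the 3 wild-type libraries, and SCL28 lies at 15.4 against 43.2 CPM.

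The SIM and SMR genes, plant inhibitors of cyclin-dependent kinases (CDKs), included a called member. SMR2 fell from 2.42 ± 0.571 to 0.4 ± 0.0346 CPM, a log2 fold change of -1.69 ± 0.22 with a limma adjusted p = 0.0344. Adjusted over the list alone, 3 of 11 tested members passed, namely SMR2, SMR7 and SMR6. SMR7 was at 1.72 ± 0.433 CPM in wild type and 0.49 ± 0.145 CPM in scl28-3, and SMR6 at 1.16 ± 0.223 and 0.353 ± 0.14 CPM. SMR13 had a log2 fold change of -0.72 ± 0.30 and did not pass. Of 3 members too low to be tested, SMR9 was at 0.6, 0.96 and 0.53 CPM in wild type and at 0, 0.07 and 0 CPM in scl28-3, and was not called with no filter (limma adjusted p = 0.135). The genotypes overlapped for the other 2, with SMR5 at 0.17, 0.29 and 0.26 against 0.29, 0.21 and 0.3 CPM and SMR12 at 0.26, 0.67 and 0.44 against 0.36, 0.35 and 0.3 CPM. The abundant members did not pass, with SIM at 48.5 ± 10.3 against 47.8 ± 4.74 CPM and SMR1 at 35 ± 9.16 against 30.8 ± 4.61 CPM. As a set, 8 of 11 members were lower, with a median log2 fold change of -0.07 and a mean of -0.41. The median was -0.22 without wild-type library 1 and -0.14 without scl28-3 library 2. The mean was -0.67 with edgeR's quasi-likelihood test, -0.68 with DESeq2, and -0.58, -0.3 and -0.21 with pseudocounts of 0.1, 1 and 2 CPM. The set was called lower by camera (adjusted p = 0.00138), and not with an estimated correlation (adjusted p = 0.482). Its camera adjusted p was 0.0654 without wild-type library 3, and 0.0502 with a filter of at least 1 CPM in 3 libraries, which kept 9 members with a mean of -0.32. SMR2 was called in 1 of the 6 fits that left out a library, and in 1 of 10 fits to reads thinned to equal depth, where its limma adjusted p reached 0.126.

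KRP genes, the other family of CDK inhibitors, gave 0 called members of 7 with limma and 0 with edgeR, and 1 had an unadjusted p under 0.05. That gene was KRP6, at 8.8 ± 1.7 CPM in wild type and 5.86 ± 0.592 CPM in scl28-3, which passed with a limma adjusted p of 0.0415 when adjusted over the list alone. The set test gave a camera adjusted p of 0.809.

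Mitotic genes showed no called member. Of 18 mitotic cyclins and B-type CDKs, 10 were higher and 8 lower, with a median log2 fold change of 0.00, none had an unadjusted p under 0.05, and the camera adjusted p was 0.933. With the endodermis list level as a covariate the set was called higher in scl28-3 (camera adjusted p = 0.0282, mean log2 difference 0.12). That call is at the preset correlation, and an estimated correlation of 0.525 without the covariate gave an adjusted p of 0.989. CYCB1;1 was at 29.7 ± 5.88 CPM in wild type and 28.1 ± 4.44 CPM in scl28-3, CYCB1;2 at 47.3 ± 5.6 and 46.2 ± 2.49 CPM, CDKB1;1 at 37.3 ± 6.63 and 32.1 ± 2.68 CPM, and CDKB2;1 at 38 ± 2.44 and 40.7 ± 0.684 CPM. Of 25 other G2/M genes, 18 were higher, with a median of 0.06, which was 0.16 without wild-type library 1, 0.12 without scl28-3 library 3, -0.04 without wild-type library 3 and -0.05 without scl28-3 library 1. Of the 25, 0 were called by limma or edgeR and 3 had an unadjusted p under 0.05. Among the 25, KN, the cytokinesis syntaxin, was at 62.6 ± 7.4 against 66 ± 3.17 CPM, and 3xHMG-box2 at 123 ± 3.42 against 136 ± 6.46 CPM. OSD1, an inhibitor of the anaphase-promoting complex, was at 16.3 ± 0.513 against 20.7 ± 0.662 CPM, and CKS2, a CDK subunit, at 34.3 ± 2.66 against 28.2 ± 1.3 CPM. This second list had a camera adjusted p of 0.259, which became 0.00189 without wild-type library 1 and 0.00666 without scl28-3 library 3. Its direction turned without wild-type library 3 (0.747) and without scl28-3 library 1 (0.765), and with the covariate it was called higher (1.62e-05, mean 0.18). These calls are at the preset correlation, while for this list the correlation was estimated at 0.488, which without the covariate gave an adjusted p of 0.973, and fry gave 0.903.

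**Figure D2:**
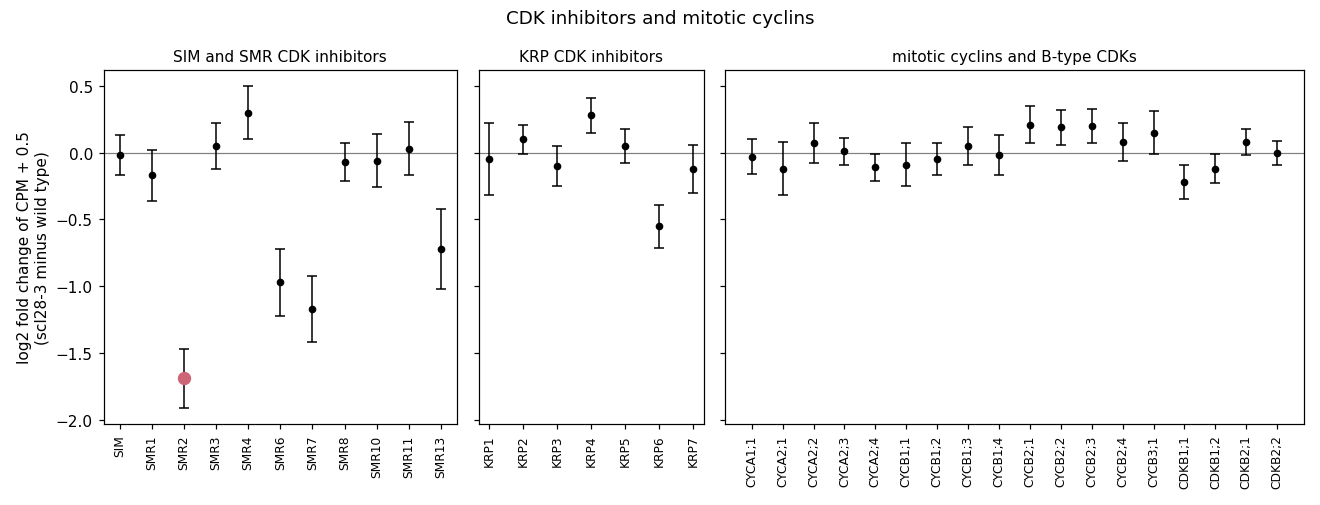
Log2 fold change of CPM + 0.5, scl28-3 minus wild type (vertical axis), for each tested member of 3 gene lists, with points for the estimate, bars for the standard error and a coloured point for a gene called over all genes. SMR2 is the coloured point at -1.69, while the mitotic cyclins and B-type CDKs lie between -0.22 and 0.21.

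The DNA damage response list had 9 of 11 tested members lower and none called over all genes by limma or edgeR, with 3 at an unadjusted p under 0.05. Adjusted over the list alone, those 3 passed, among them TSO2 and SMR7. TSO2, a small subunit of ribonucleotide reductase, was at 155 ± 10.5 CPM in wild type and 111 ± 3.92 CPM in scl28-3 (limma adjusted p = 0.171 over all genes). XRI1 was at 33.1 ± 4.17 and 28.3 ± 1.78 CPM, a log2 fold change of -0.24 with a limma adjusted p = 0.994 over all genes. The set was called lower by camera (adjusted p = 3.21e-05), and not with an estimated correlation (adjusted p = 0.482) or with the endodermis list level as a covariate (camera adjusted p = 0.0514), where the mean log2 difference went from -0.29 to -0.2. TSO2, SMR7 and CYCB1;1 also stood in other lists. Of 24 DNA replication and S phase genes, 18 were lower, with 0 called, and TSO2 passed adjusted over the list alone. RNR1 was at 91.9 ± 16.1 and 87.7 ± 5.94 CPM. This set had a camera adjusted p of 0.0127 and an adjusted p of 0.973 with an estimated correlation. Its direction turned without wild-type library 1 (adjusted p = 0.6) and with the endodermis list level as a covariate (0.288), where the mean log2 difference went from -0.09 to 0.05, and without scl28-3 library 3 its adjusted p was 0.163.

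In the core histone list 14 of 16 tested members were lower, with a median log2 fold change of -0.10. Limma and edgeR called 0 members, and none had an unadjusted p under 0.05. The list held only genes that the reference names HTA, HTB or HTR, so other histone genes were not covered. CENH3, the centromeric histone, also stood in the list of other G2/M genes. HTB4 was at 372 ± 23 and 356 ± 21.8 CPM, and HTB11 at 265 ± 9.57 and 236 ± 18.8 CPM. The camera adjusted p was 0.00749, and the adjusted p = 0.93 with an estimated correlation. It was 0.315 without wild-type library 2, 0.0744 without wild-type library 3 and 0.115 without scl28-3 library 3.

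Of 38 tested expansins and XTH enzymes, which loosen and remodel cell walls, 26 were lower and XTH5 was called. Adjusted over the list alone, 4 passed, and beside XTH5 these were EXPA10, XTH21 and EXPA15. EXPA10 was at 8.75 ± 3.64 and 2.5 ± 0.974 CPM, XTH21 at 48 ± 2 and 37.9 ± 0.549 CPM, and EXPA15 at 75.2 ± 12 and 51.9 ± 6.56 CPM. The most abundant members, EXPA9 and XTH8, were at 299 ± 24.4 against 255 ± 18.5 CPM and at 193 ± 7.23 against 174 ± 13.8 CPM. The camera adjusted p was 0.00171, and the adjusted p = 0.616 with an estimated correlation. Without wild-type library 3 it was 0.101.

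Endodermis and root hair genes were called higher in scl28-3 as sets by camera at the preset correlation, and not with an estimated correlation (adjusted p = 0.74 for both), while no single member passed. All 9 endodermis genes were higher, with a median log2 fold change of 0.43, which was 0.07 without wild-type library 1, 0.71 without wild-type library 3 and 0.25 without scl28-3 library 3. Of the 9, 0 were called by limma or edgeR and 2 had an unadjusted p under 0.05. CASP1, a protein of the Casparian strip, was at 58.3 ± 31 CPM in wild type and 76 ± 24.6 CPM in scl28-3, and ESB1 at 69.8 ± 29.8 and 87.7 ± 20.4 CPM. For this list the camera adjusted p was 0.000114. Leaving out wild-type library 1 gave a camera adjusted p of 0.235. Of 11 root hair genes, 10 were higher, with 0 called by limma or edgeR and 1 at an unadjusted p under 0.05. RHD2, an NADPH oxidase of root hairs, was at 83.5 ± 11.7 and 90.5 ± 5.08 CPM, and PRP3 at 58.7 ± 11.9 and 77.4 ± 15.2 CPM. Their camera adjusted p was 0.00329. With the endodermis list level as a covariate it was 0.315, and the mean log2 difference went from 0.23 to 0.07. The camera adjusted p of the root hair list was 0.115 without wild-type library 2 and 0.101 without scl28-3 library 3. Leaving out a library moved its mean log2 difference between 0.13 (without scl28-3 library 3) and 0.36 (without wild-type library 3). That mean was 0.14 without wild-type library 1. The mean level of the endodermis list, relative to the mean of all 6 libraries, was -0.86, -0.06 and 0.27 in wild type and 0.04, 0.06 and 0.56 in scl28-3.

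**Figure D3:**
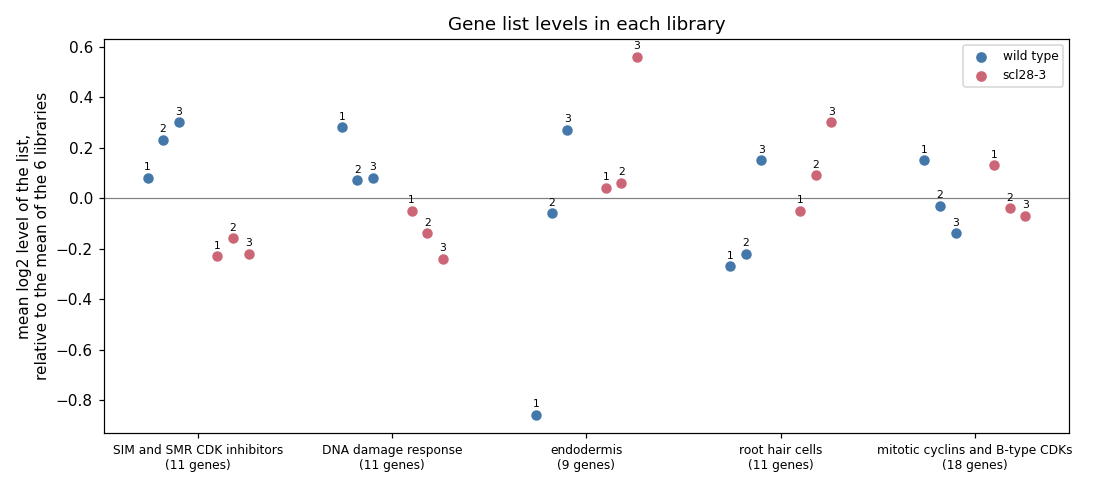
Mean log2 level of 5 gene lists in each library relative to the mean of the 6 libraries (vertical axis), with blue points for wild type, red points for scl28-3 and the library number above each point. The SIM and SMR list lies above 0 in the 3 wild-type libraries and below 0 in the 3 scl28-3 libraries, while the endodermis list ranges from -0.86 to 0.27 within wild type.

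The libraries were not ordered mainly by genotype. The first principal component held 44.3% of the variance and set wild-type library 1 (-35.6) apart from wild-type libraries 2 and 3 (3.4 and 17.3), with the scl28-3 libraries at -9.4, 4.9 and 19.5. The second held 21% and placed the wild-type libraries at 1.7, 21.9 and 9.4 and the scl28-3 libraries at -13.5, -5.4 and -14.1. The called genes did not gather near SCL28. None of the other 12 lay within 5 Mb of it, where 1614 tested genes lie, against 12 of 16224 tested genes elsewhere (Fisher's exact test, two-sided, p = 0.617).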

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

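The quasi-likelihood test, the other pseudocounts, the thinned reads and the endodermis covariate were chosen after seeing the data. SCL28 stayed called and lower under all 20 alternatives, from -1.59 to -1.40 (log2), with a highest adjusted p of 0.0329. The count of genes lower in scl28-3 (13) was 38 with the edgeR exact test, 24 with the endodermis covariate, 5 at an adjusted p under 0.01, and 5 to 18 when a library was left out. The count higher (0) was 8 with the exact test and 3 with the covariate. Fits with fewer libraries have less power, which does not account for the rise to 18 without wild-type library 1. Otherwise the cause was not tested. No called gene reversed. Called genes lost their call in 44 gene and setting pairs, and in 11 pairs a named gene that was not called (TSO2, EXPA10, SMR7 or EXPA15) gained one. DESeq2, whose 18 calls include the 13 of the main test, also gave 0 other called genes within 5 Mb of SCL28. Windows of 1 and 2 Mb lie inside that of 5 Mb, so their count of 0 was fixed in advance. Low genes rest on few reads, which limits their precision.

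With the sample numbers as a replicate block, 40 genes were called lower and 24 higher. The numbers were not shown to pair the samples, since deviations of same-numbered libraries correlated at 0.44, 0.04 and 0.5, and not every library correlated best with its own number.

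Of the gene lists, 7 were called at the preset correlation and 0 with an estimated correlation or fry. With an estimated correlation the adjusted p was 0.482 for DNA damage and for SIM and SMR, 0.973 for S phase, 0.74 for root hair and endodermis, 0.93 for histones and 0.616 for wall enzymes. With fry these were 0.386, 0.214, 0.877, 0.774, 0.774, 0.804 and 0.508. With the endodermis covariate, DNA damage was at 0.0514, root hair at 0.315, S phase reversed at 0.288, and mitotic cyclins (0.0282), division plane (0.00139) and other G2/M genes (1.62e-05) were called higher in scl28-3. SIM and SMR was at 0.0502 with a CPM of at least 1. When a library was left out, the adjusted p ran from 0.139 to 0.909 for mitotic cyclins, 0.00189 to 0.765 for other G2/M, 9.88e-05 to 0.6 for S phase, 0.000443 to 0.0654 for SIM and SMR, 4.04e-05 to 0.115 for root hair, 2.28e-07 to 0.235 for endodermis, 0.000443 to 0.315 for histones and 8.88e-05 to 0.101 for wall enzymes, where the first 3 reversed at least once. For DNA damage the adjusted p ran from 2.39e-06 to 0.0171 when a library was left out, at the preset correlation. The causes were not tested.

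Heat shock gained a call with the block (0.0273) and when a library was left out (lowest 0.0068, highest 0.875), and phloem when a library was left out (0.0349 to 0.294). With an estimated correlation and all 6 libraries the camera adjusted p was 0.973 for heat shock and 0.616 for phloem. It was 0.973 for xylem and cytokinin lists and 0.989 for division plane, which also gained a call when a library was left out. Lists that were not called turned direction in some settings. Leaving out a library did so for division plane (0.0125 to 0.911), endocycle (0.163 to 0.983), cell cycle regulators (0.298 to 0.945), root meristem (0.239 to 0.983), root cap (0.335 to 0.796), xylem (0.0212 to 0.887), photosynthesis (0.0842 to 0.747), jasmonate (0.494 to 0.954), immune (0.394 to 0.765), phosphate (0.222 to 0.971), iron (0.112 to 0.966), hypoxia (0.254 to 0.983) and cytokinin lists (0.00843 to 0.897). The covariate did so for cell cycle regulators (0.288), root meristem (0.0873), xylem (0.315), photosynthesis (0.0745), heat shock (0.441), immune (0.296), phosphate (0.992) and iron lists (0.966). With the library total, cell cycle regulators, root meristem and root cap were at 0.993. With no filter, cell cycle regulators, root meristem and immune were at 1 and hypoxia at 0.648. Root meristem was at 0.961 with the stricter filter, 0.976 with the block and 0.929 thinned, immune at 0.936 thinned, root cap at 0.952 with voom and 0.996 with the block, and cell cycle regulators at 0.986 with fry.

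Among named genes that were not called, the log2 fold change crossed 0 when a library was left out for SIM (-0.22 to 0.08), CYCB1;1 (-0.21 to 0.06), CYCB1;2 (-0.16 to 0.01), KN (-0.04 to 0.14), RNR1 (-0.20 to 0.05) and CASP1 (-0.03 to 0.84). With the covariate it was 0.13 for CYCB1;1, 0.07 for CYCB1;2, 0.10 for RNR1, -0.18 for CASP1 and -0.11 for ESB1, and CYCB1;2 was at 0.01 thinned.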

Other observations

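The tests of the share of differentiating tissue and of wild-type library 1 for the endodermis list, of position, of noncoding loci and of fold changes after thinning, and the count of splits for the called genes, were chosen only after the result was seen.

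The genes with large loadings on the first principal component included CASP1 and EXPA10 and several genes of flavonoid synthesis, which are in no fixed list, were not tested for enrichment and were picked after their values were seen. Wild-type library 1 held 314.86 CPM of FLS1, 103.34 CPM of TT5 and 74.74 CPM of TT7. The other wild-type libraries held 124.13 and 111.09 CPM of FLS1, 44.33 and 27.99 CPM of TT5, and 27.5 and 20.62 CPM of TT7. Among the scl28-3 libraries, library 1 was highest, with 198.18 CPM of FLS1 against 114.71 and 112.8 CPM.

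Other lists gave no call over all genes with limma or edgeR. Phloem genes were higher in 6 of 7 (camera adjusted p = 0.107, and 0.0349 without scl28-3 library 2) and xylem and secondary wall genes in 10 of 11 (0.174, with 0.0212 without wild-type library 3 and 0.0258 without scl28-3 library 1). These values are at the preset correlation. With an estimated correlation and all 6 libraries the camera adjusted p was 0.616 for phloem and 0.973 for xylem. At the preset correlation the camera adjusted p was 0.246 for heat shock (0.0131 without wild-type library 3 and 0.0068 without scl28-3 library 2), 0.247 for A-type ARRs of the cytokinin response (0.00843 without wild-type library 2), 0.435 for auxin response and transport, and 0.721 for endocycle genes and for iron deficiency. With an estimated correlation and all 6 libraries it was 0.973 for heat shock and for A-type ARRs. The preset correlation gave 0.764 for division plane and microtubule organisation (0.0125 without wild-type library 1), phosphate starvation and hypoxia, 0.809 for non-hair epidermis and 0.818 for photosynthesis. For division plane an estimated correlation with all 6 libraries gave 0.989. The camera adjusted p at the preset correlation was 0.821 for jasmonate and wounding and for the immune response, and 0.979 for the root meristem, the root cap, and cell cycle regulators with D-type cyclins. Median and mean differed in sign for the immune response (0.11 and -0.01), iron deficiency (0.15 and -0.01) and non-hair epidermis (-0.01 and 0.03), and the test of the cell cycle regulators pointed down with a median of 0.01.

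The higher endodermis and root hair lists may reflect how much differentiating tissue each tip piece held. The level of the endodermis list ranged by 1.12 within wild type and by 0.52 within scl28-3, both above the 0.44 between genotypes (log2). Wild-type library 1 carries much of the endodermis difference, since without that library the camera adjusted p of this list was 0.235. The root hair list stayed called without it (camera adjusted p = 0.0393). That list lost its call without wild-type library 2 (0.115) or scl28-3 library 3 (0.101). An effect of the genotype on differentiation stays open and was not tested.

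That every gene called in the limma fit was lower could have several sources. The tables argue against a region linked to SCL28, with 0 called genes other than SCL28 within 5 Mb of it. Of the 12 called genes other than SCL28, 33.3% were pseudogenes or noncoding RNAs, against 2.3% of tested genes (Fisher's exact test, two-sided, p = 0.000118), so differences between the plant lines at such loci, independent of SCL28, are a candidate explanation for these 4. Thinning all libraries to equal depth leaves the expected CPM of each gene unchanged. Thinning therefore cannot show whether depth is the source of the size of the differences. The recovered reads argue against depth for these genes, since deeper sequencing adds reads. Except for BGLU25, each called gene had fewer reads in every scl28-3 library than in every wild-type library. SCL28 had 515, 443 and 483 reads in wild type and 248, 212 and 229 in scl28-3. BGLU25 overlapped, with 984, 789 and 921 against 711, 753 and 874 reads. The mean log2 difference of the 13 genes was -1.84 before thinning and between -1.88 and -1.83 after it in 10 draws. Their mean SE was 0.19 before and 0.2 to 0.21 after, and 8 to 12 of the 13 were called, so how many pass at equal depth stays open. An effect of SCL28 itself stays open for all of them and was not tested apart from the line.

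The lower SIM and SMR list would need a deeper measurement. An unequal share of endodermis, as tracked by the 9 members of its list, is argued against. The mean log2 difference of the SIM and SMR list was -0.47 with the endodermis level as a covariate and -0.41 without. That covariate was lowest in wild-type library 1 (-0.86) and does not measure other differentiating tissues, whose share stays open. The same covariate ended the call of the DNA damage list (camera adjusted p = 0.0514) and gave calls higher in scl28-3 for mitotic cyclins (0.0282), division plane (0.00139) and other G2/M genes (1.62e-05), all at the preset correlation, so other lists depend on it. Thinning cannot show whether depth is the source of the size of the SIM and SMR difference, since it leaves expected CPM unchanged. The mean over the same 11 members was between -0.46 and -0.37 in 10 thinned draws. Their mean SE was 0.21 before and 0.2 to 0.22 after. The camera adjusted p was under 0.05 in 6 of those draws. It ran from 0.00157 to 0.00815 in draws that left 10 members to test and from 0.0299 to 0.111 in draws that left 9, so the call ended only in draws where the filter on low counts had removed 2 members. Whether the list passes at equal depth stays open. An effect of the genotype on these genes stays open.

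Dividing the 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05. The real split called 13 genes and the highest of the others 2, so 1 split reached the real count. For lists called by camera at the preset correlation, the real split gave 7 and the highest other 12, and 6 of the 10 splits gave at least as many. The split of wild-type libraries 1 and 2 with scl28-3 library 1 against the rest had 2402 genes at an unadjusted p under 0.05, against 781 in the real split, which points to a structure of the samples other than genotype.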
